A study of Schizosaccharomyces pombe with 24 samples.

How the data were processed

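Gene expression was measured by polyA+ RNA-seq in haploid fission yeast (Schizosaccharomyces pombe) grown to log phase at 30 °C in rich YES medium. The series holds 24 libraries in 8 groups of 3 biological replicates each: a wild-type control (WT) and 7 mutants carrying single amino acid changes in subunits of the machinery that cleaves and polyadenylates pre-mRNA. The groups and replicate numbers were taken from the sample labels. Per the labels, 5 mutants (msi2-G252E, pfs2-E104A, pfs2-V180F, pta1-T524M and ysh1-L74F) also carry a kanMX marker beside a wild-type copy of asp1, pla1-Y86L has its own kanMX marker, and cft1-L249Q is the h+ strain among h- strains.

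Libraries were made with a directional kit and sequenced in pairs of reads, per the labels' protocols. The authors deposited raw read counts per gene for the 24 libraries. HISAT2 2.1.0, SAMtools, HTSeq 0.10.0 and DESeq2 are named with genome build ASM294v2, per the submitters' processing notes. The strand setting of the counting and the annotation release were not given in the sources used here, so the counts of a gene and of a gene antisense to it, or overlapping it, are uncertain to that extent. The authors also deposited 7 comparison tables, each of a mutant against WT. Per the file headers, they hold a mean signal over libraries (baseMean), log2 fold changes with standard errors, and p-values with adjusted p-values from the authors' DESeq2 test. The test statistic columns of those 7 tables were not used. The reference annotation at hand is of another assembly, ASM294v3, so no coordinates are given and it served only for gene names and neighbours. It matched 6836 of the 6988 identifiers in the count table.

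Total counts ran from 19.4 to 29.3 M per library, with a median of 25.45 M. No gene took more than 1.65% of a library. The common biological coefficient of variation was 4.9%. Replicates were compared before they were averaged. Over genes with at least 20 reads in a pair, the chi-square per degree of freedom of the 24 replicate pairs ran from 2.6 to 23.8, so no pair was within sampling noise and all libraries were counted separately.

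Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with too few reads were removed with filterByExpr, leaving 6287 genes. Library sizes were scaled with TMM, a quasi-likelihood model with 1 mean per group was fitted to all 24 libraries (16 residual degrees of freedom), and each mutant was tested against WT. The pfs2 alleles were also tested against each other. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. A second count took genes that were also at least 2-fold apart. A gene called specific to a mutant passed both thresholds, in the same direction, against WT and against the mean of the other 6 mutants, so it can also be changed in some of those. Genes shared by mutants passed both thresholds in the same direction in each. P-values measure the spread between biological replicates as labelled.

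Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. There were 26 lists, 19 fixed by symbol and 7 by rule. They were tested with camera (limma) at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 182 tests of each kind. One list is not reported here, though it is counted in the totals. The others are the PHO genes; other phosphate and inositol pyrophosphate genes; cleavage, polyadenylation and termination factors; thiamine-regulated genes; Mmi1-eliminated meiotic transcripts; sexual differentiation and nitrogen starvation genes; P-cell-specific and M-cell-specific mating genes; iron starvation-induced genes; iron-using genes repressed by Php4; copper and zinc genes; core environmental stress genes; heat shock chaperones; ribosome biogenesis factors; histone genes; flocculin-type cell surface genes; carbon source genes; Tf2 retrotransposons; cytosolic ribosomal proteins; lncRNA genes; snoRNA and snRNA genes; subtelomeric genes; and 3 classes of gene by neighbour.

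For each mutant the text names the mutated gene, asp1, pho1, pho84 and tgp1. It also names the largest changes among genes at least 2-fold apart whose mutant libraries all lie on the same side of the WT libraries (8 protein-coding genes with a symbol and 2 other genes per direction), and up to 4 called members per list. Some were left out for length. The 6 largest differences per direction between the pfs2 alleles, up to 15 genes shared by at least 5 mutants, and the 4 largest specific genes per mutant follow the same rule. Genes named outside the rule are said to be chosen after their values were seen.

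The scripts were tested on simulated counts with 200 changed genes per mutant among 6287, of which 6256 passed the filter. Over the 7 simulated comparisons with WT, the recovered share of genes changed 1.5-fold was 81.2 to 94.4%, of genes changed 2-fold 89.6 to 100%, and of genes changed 4-fold 97.1 to 100%. The highest share of false calls was 4.17%. A planted list was found in all 7 simulated mutants, and 7 of 175 tests of other lists also passed, as many as for the planted list. At the preset correlation, the adjustment thus did not hold the share of false list calls under 0.05. A list call at that setting alone is therefore weak.

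Alternatives were other size factors (RLE), no filter, a stricter filter of at least 50 reads in at least 3 libraries, DESeq2 1.42.0, a fit of only the 6 libraries compared, the replicate number as a block, protein-coding genes only, a 1.5-fold threshold, an estimated correlation for list tests, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.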

Results

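The data are polyA+ RNA-seq read counts from log-phase fission yeast, with 3 biological replicates of WT and of each of 7 mutants. The mutations lie in 6 subunits of the cleavage and polyadenylation machinery, which cuts nascent transcripts at their 3' ends and adds the poly(A) tail: Cft1, Msi2, Pfs2 (2 alleles), Pla1 (the poly(A) polymerase), Pta1 and Ysh1 (the endonuclease). Each WT library held 25.3 to 28.1 M counts. The mutant libraries held 19.4 to 29.3 M. By its title, the series concerns suppression of precocious transcription termination by mutations of this kind. Each comparison below asks how the transcriptome of a mutant differed from WT.

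The labels were checked against the counts as far as gene counts allow. A point mutation is not seen in a gene count, so the level of the mutated gene checks little. The mutated gene's mRNA differed from WT by a log2 fold change of 0.13 ± 0.04 (SE) in cft1-L249Q, -0.01 ± 0.05 in msi2-G252E, -0.13 ± 0.05 in pfs2-E104A, -0.15 ± 0.05 in pfs2-V180F, 0.10 ± 0.03 in pta1-T524M and -0.04 ± 0.03 in ysh1-L74F. The pfs2 calls were lost in pfs2-E104A without its replicate 2 or 3 or WT replicate 1, and in pfs2-V180F without its replicate 1 or WT replicate 1. The pta1 call in pta1-T524M was lost without its replicate 1 or 3 or WT replicate 2. In pla1-Y86L, whose label places a marker at the mutated gene, pla1 fell by 2.08 ± 0.04 on the log2 scale. SPNCRNA.1398, annotated antisense to pla1 and chosen after its values were seen, rose there by 1.97 ± 0.09. The marker, the lower pla1 mRNA and the Y86L change coincide in pla1-Y86L, so its differences from WT are not separated between them. SPNCRNA.1144, annotated antisense to asp1, rose in the 5 strains whose labels give a kanMX marker at asp1, by log2 fold changes of 4.37 to 5.36. It was at 0.31 in pla1-Y86L and 0.54 in cft1-L249Q, neither called. The asp1 mRNA itself, which encodes an inositol pyrophosphate kinase and phosphatase, was higher by 0.21 to 0.57 in the marked strains. It fell by 0.34 in pla1-Y86L and stood at -0.03 in cft1-L249Q. WT carries neither marker. The M-factor precursor gene mfm2 fell by 4.57 ± 0.15 in the h+ strain cft1-L249Q.

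**Figure D1:**
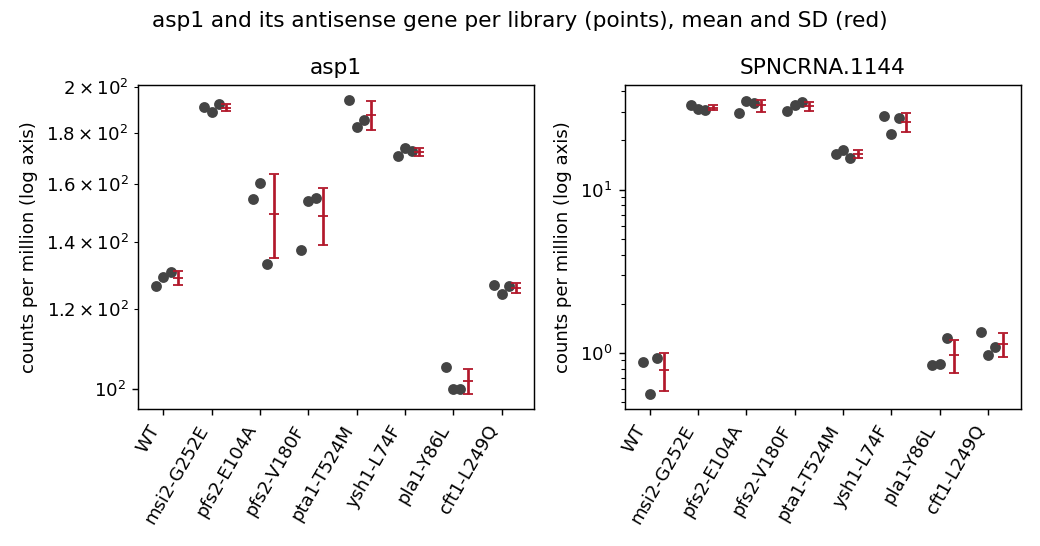
CPM on a log axis for asp1 and SPNCRNA.1144 in each library (points) with the group mean and SD (red, n = 3). SPNCRNA.1144 is at or above 412 reads in every library of the 5 marked strains and at or below 36 reads in every library of WT, pla1-Y86L and cft1-L249Q.

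The number of changed genes differed widely between mutants. Most were changed in pla1-Y86L, with 4063 genes at adjusted p under 0.05, and fewest in ysh1-L74F, with 906. Between them lay msi2-G252E with 3697, pfs2-V180F with 3023, cft1-L249Q with 2723, pta1-T524M with 2416 and pfs2-E104A with 2152. At least 2-fold higher and lower were 305 and 128 genes in pla1-Y86L, 276 and 102 in msi2-G252E, 155 and 56 in pfs2-V180F, 105 and 56 in cft1-L249Q, 77 and 60 in pta1-T524M, 46 and 45 in pfs2-E104A, and 17 and 9 in ysh1-L74F. The ysh1-L74F count of 906 moved to 411 without its replicate 1, 415 without its replicate 2 and 585 without WT replicate 3.

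**Figure D2:**
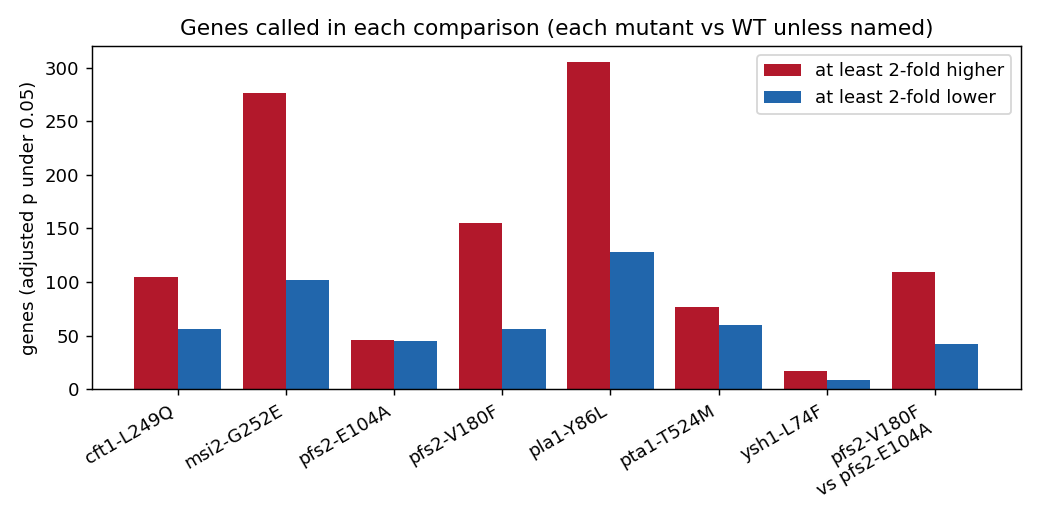
Number of genes at least 2-fold higher (red) or lower (blue) at adjusted p under 0.05 in each comparison, with the bars starting at 0. The highest bar is 305 genes in pla1-Y86L and the lowest is 9 in ysh1-L74F.

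The PHO genes were lower in most mutants. They encode the acid phosphatase Pho1, the phosphate transporter Pho84 and the glycerophosphodiester transporter Tgp1, and each is repressed in cis by transcription of an upstream lncRNA. The pho1 mRNA was at 1208 ± 72.1 CPM (counts scaled to library size; SD, n = 3) in WT, and fell by 3.24 ± 0.09 (log2, SE) in msi2-G252E, by 3.10 ± 0.09 in pfs2-V180F, by 2.34 ± 0.08 in cft1-L249Q, by 2.14 ± 0.08 in pta1-T524M, by 1.93 ± 0.08 in pfs2-E104A, by 1.54 ± 0.08 in ysh1-L74F and by 0.52 ± 0.08 in pla1-Y86L. The pho84 mRNA, at 1489 ± 53.8 CPM in WT, fell by 2.67 in pfs2-V180F, 2.13 in msi2-G252E, 1.97 in cft1-L249Q, 1.66 in pfs2-E104A, 1.01 in pta1-T524M, 0.98 in ysh1-L74F and 0.93 in pla1-Y86L, with SE of 0.08. The tgp1 mRNA moved less, falling by 0.77 in pta1-T524M, 0.75 in pfs2-E104A, 0.62 in msi2-G252E, 0.35 in cft1-L249Q, 0.30 in pfs2-V180F and 0.27 in ysh1-L74F, with SE of 0.07. In pla1-Y86L tgp1 was 0.18 ± 0.07 higher (adjusted p = 0.0219). The tgp1 call was lost in pla1-Y86L without its replicate 3 (0.16) or WT replicate 2 (0.14), and in ysh1-L74F without its replicate 1 (-0.25) or WT replicate 1 (-0.23).

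As a list, the 3 PHO genes were lower than other genes in 6 mutants, with adjusted p from 7.1e-23 in pfs2-E104A to 5.8e-12 in msi2-G252E. All 6 calls held with an estimated correlation, the highest adjusted p being 0.00091. In each of the 6, all 3 genes fell, over all genes tested and adjusted over the list alone. Of these mutants, 5 carry the asp1 marker, which WT lacks, so there the falls are not separated from it. pho1 and pho84 also fell in cft1-L249Q and pla1-Y86L, which lack the asp1 marker. In pla1-Y86L the list did not pass (adjusted p = 0.288).

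**Figure D3:**
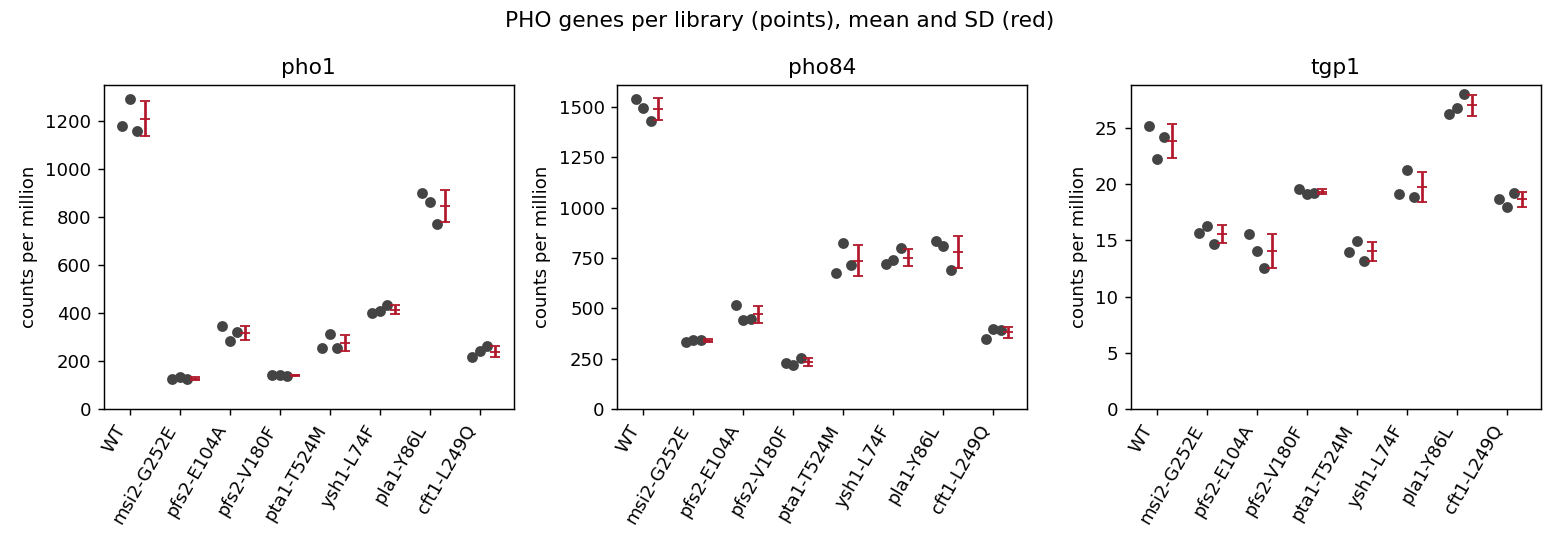
CPM for pho1, pho84 and tgp1 in each library (points) with the group mean and SD (red, n = 3), on axes starting at 0. The pho1 mean is 1208 in WT and 128 in msi2-G252E, its lowest.

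The lncRNAs upstream of the PHO genes, chosen after their values were seen, went different ways. In msi2-G252E, nc-pho1 rose by 1.73 ± 0.09 and prt2, upstream of pho84, by 1.33 ± 0.05, while nc-tgp1 fell by 0.23 ± 0.07. That nc-tgp1 call was lost without replicate 3 of the mutant or WT replicate 1. In pla1-Y86L nc-pho1 rose by 2.76 ± 0.09, prt2 by 0.50 ± 0.05 and nc-tgp1 by 1.58 ± 0.07. In pfs2-V180F nc-pho1 rose by 0.93 ± 0.10 and prt2 by 1.05 ± 0.05, with nc-tgp1 lower by a log2 fold change of -0.37 ± 0.08. In pfs2-E104A nc-pho1 was at -0.01 ± 0.11 (adjusted p = 0.975), prt2 rose by 0.48 ± 0.05 and nc-tgp1 was lower at -0.50 ± 0.08. In cft1-L249Q, pta1-T524M and ysh1-L74F, nc-pho1 rose by 0.67, 0.42 and 0.68 and prt2 by 0.66, 0.18 and 0.63. nc-tgp1 was lower in cft1-L249Q (-0.48) and pta1-T524M (-0.44), and at -0.21 in ysh1-L74F (adjusted p = 0.0573).

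Of the 13 other phosphate and inositol pyrophosphate genes tested, vtc4 and vtc2, subunits of the vacuolar polyphosphate polymerase, fell in all 7 mutants, though the vtc4 call in ysh1-L74F was lost without WT replicate 3. The vtc4 change was strongest in pfs2-V180F at -1.05 and in msi2-G252E at -1.03. The phosphate transporter gene pho842 fell by 1.25 in pfs2-E104A. The list passed as lower in cft1-L249Q (5 fell, 1 rose; adjusted p = 0.0157, or 0.392 with an estimated correlation), pfs2-E104A (5 fell, 1 rose; adjusted p = 0.00017, or 0.206 with an estimated correlation) and pfs2-V180F (6 fell, 2 rose; adjusted p = 0.0167, or 0.392 with an estimated correlation). These counts were equal when adjusted over the list alone.

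In cft1-L249Q, the largest rises of protein-coding genes with a symbol, among those whose mutant libraries all lie on the same side of WT, were in tlh1 and tlh2, subtelomeric RecQ-type helicase genes, followed by rtc3 and gst2. For tlh1, 73 reads over the 3 mutant libraries stood against 2 in WT, a 38.4-fold ratio with a 95% interval of 10.2 to 323 that covers counting error only. tlh2 rose by 3.84 ± 0.55, rtc3 by 1.98 ± 0.17 and the glutathione S-transferase gene gst2 by 1.88 ± 0.08. tlh1 and tlh2 are near-identical copies, so reads could be split between them. By the same filter the largest falls were in mfm2, in guf1 (-2.48 ± 0.10), which encodes a GTPase, in ftm2 (-2.36) and in pho1. SPNCRNA.388 fell by 6.03 ± 0.36 and SPBC23G7.10c, a flavin oxidoreductase gene beside the mating-type locus as is SPNCRNA.388, by 3.54 ± 0.39.

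Of 7 M-cell-specific mating genes tested in cft1-L249Q, 3 fell and 2 rose (4 and 3 adjusted over the list alone), and the list passed as lower (adjusted p = 1.1e-05, or 0.026 with an estimated correlation). Besides mfm2, the pheromone receptor gene mam2 fell by 1.35 and mam1 by 0.71. Another M-factor precursor gene, mfm3, chosen after its values were seen, went the other way and rose by 0.61. That call was lost in 3 of 6 fits without 1 library. Of 4 P-cell-specific genes, map1 fell by 0.56 and the others did not pass. The list was fixed with 7, and its P mating-type genes at mat1 were not analysed here. Of 18 core environmental stress genes, 13 rose and 1 fell, with gst2 and srx1 (1.07) the largest (adjusted p = 1.2e-08, or 0.107 with an estimated correlation). Of 12 heat shock chaperones, 8 rose and 1 fell (adjusted p = 0.00059, or 0.337 with an estimated correlation). Of 141 cytosolic ribosomal protein genes, 123 fell and 1 rose (127 and 1 adjusted over the list alone), led by rpl1602 (-1.82), rps001 (-1.54) and rps1002 (-1.40), with a list median of -0.29 (adjusted p = 5.5e-26, or 0.392 with an estimated correlation).

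In msi2-G252E the genes that cells induce when starved of iron were strongly higher. Of 11 tested, 10 rose, both over all genes and adjusted over the list alone. The siderophore transporter gene str3 rose by 8.26 ± 0.33, shu1 (heme uptake) by 8.07 ± 0.13, the ferric reductase gene frp1 by 5.76 ± 0.21, the iron transporter genes fio1 by 4.88 ± 0.23 and fip1 by 4.83 ± 0.21, and str1 by 4.19 ± 0.31. sib3, at -0.06, did not pass. The list median was 4.19 (adjusted p = 7.6e-24, or 0.00023 with an estimated correlation). Of 10 iron-using genes repressed by Php4, 7 fell and 1 rose, led by pcl1 (-1.01) and cyc1 (-0.96) (adjusted p = 3.0e-07, or 0.0839 with an estimated correlation). php4 itself rose by 1.41.

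**Figure D4:**
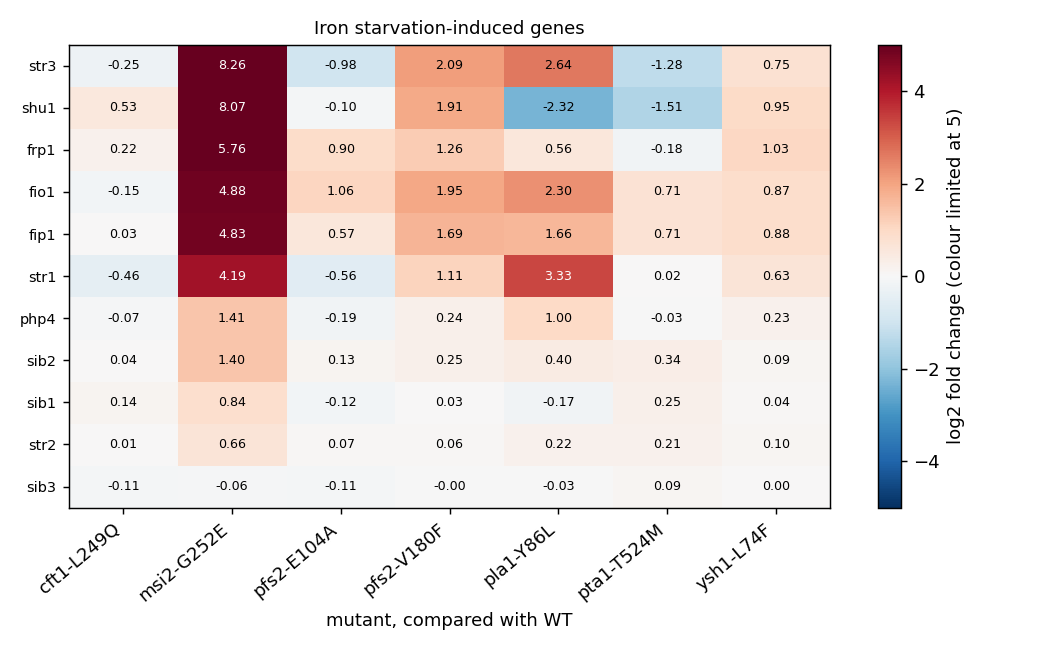
Log2 fold change against WT of each of the 11 iron starvation-induced genes (rows) in each mutant (columns), with the colour scale limited at 5. In msi2-G252E str3 reaches 8.26 and sib3 is at -0.06; in cft1-L249Q the values lie between -0.46 and 0.53.

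Among other genes in msi2-G252E, pho1 fell most of the protein-coding genes with a symbol whose mutant libraries all lie on the same side of WT, followed by guf1 (-2.85 ± 0.11) and gep4 (-2.16 ± 0.13). tlh1 had 142 reads against 2 in WT, a 68.7-fold ratio with a 95% counting interval of 18.7 to 573. Of 1190 lncRNA genes, 467 rose and 162 fell (466 and 155 adjusted over the list alone; adjusted p = 7.9e-05, or 0.137 with an estimated correlation), with SPNCRNA.1258 at 4.73 ± 0.23 and SPNCRNA.1156 at -4.35 ± 0.21. SPNCRNA.1258 is annotated as a possible alternative untranslated region of an mRNA. Counts assigned to lncRNA genes made up 1.42 ± 0.0359% of the total (SD, n = 3), against 1.05 ± 0.0212% in WT. Of 18 core stress genes 13 rose and 1 fell, led by srx1 (2.45) and gst2 (2.18) (adjusted p = 0.001, or 0.345 with an estimated correlation). Of the ribosomal protein genes, 135 fell and 1 rose (median -0.37; adjusted p = 9.4e-15, or 0.586 with an estimated correlation). Of 42 snoRNA and snRNA genes, 20 rose and 2 fell (adjusted p = 0.0282, or 0.649 with an estimated correlation). That call was also lost without replicate 2 (adjusted p = 0.0991) or 3 (0.0647) of the mutant, or WT replicate 3 (0.103). Counts from polyA+ libraries do not separate the level of these RNAs from their polyadenylation.

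In pfs2-E104A, several hexose transporter genes changed. ght5, the high-affinity glucose transporter gene, rose by 1.97 ± 0.22, with ght1 (1.12 ± 0.15) and ght4 (1.08 ± 0.11) also higher and ght3 lower (-1.45 ± 0.21). The 14 carbon source genes as a list did not pass (5 rose, 1 fell; adjusted p = 0.112). The aldehyde dehydrogenase gene atd1 fell by 2.12 ± 0.14, and hem13 (heme synthesis) rose by 1.23 ± 0.13. Of 17 ribosome biogenesis factors, 12 fell and none rose, by edgeR over all genes or adjusted over the list alone, with mak16 at -0.46 (adjusted p = 2.3e-05, or 0.448 with an estimated correlation). Of 141 ribosomal protein genes, 16 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0247, or 0.838 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.104) or 2 (0.0612). Of 5 Tf2 retrotransposon genes, which are near-identical copies, 3 rose (adjusted p = 0.0259, or 0.137 with an estimated correlation). That call was lost without replicate 3 of the mutant (adjusted p = 0.0562) and with no filter on low counts (0.0887).

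In pfs2-V180F, uracil-regulated urg1 rose by 2.16 ± 0.37, the ammonium transporter gene amt3 by 2.12 ± 0.10 and str3 by 2.09 ± 0.55. ftm4 had 1 read in the mutant against 206 in WT, a ratio of 0.00491 with a 95% counting interval of 0.000124 to 0.0277, and pdc102 1 against 87 (0.0116, interval 0.000291 to 0.0665). Those intervals leave out the spread between WT libraries, which for ftm4 was as wide as its level (2.63 ± 2.55 CPM, SD, n = 3). For pdc102 the WT level was 1.13 ± 0.77 CPM. gdt1 fell by 3.00 ± 0.64 and guf1 by 2.97 ± 0.11. The systematic names of gdt1 (SPAC186.05c) and pdc102 (SPAC186.09) place them close together, so their falls may not be separate. Of the 11 iron starvation-induced genes 8 rose, including fio1 (1.95 ± 0.25), shu1 (1.91 ± 0.23) and fip1 (1.69), with a median of 1.11 (adjusted p = 0.00848, or 0.335 with an estimated correlation). Of 14 sexual differentiation and nitrogen starvation genes, 8 rose and 2 fell (adjusted p = 0.0134, or 0.137 with an estimated correlation). That call was lost without replicate 1 of the mutant (adjusted p = 0.0833). Core stress genes (12 rose, 3 fell, or 13 and 3 adjusted over the list alone; adjusted p = 0.000395, or 0.324 with an estimated correlation) and heat shock chaperones (9 rose, 1 fell, or 10 and 1 adjusted over the list alone; adjusted p = 7.9e-06, or 0.212 with an estimated correlation) were higher, with hsp16 at 1.21. Ribosome biogenesis factors (16 fell, or 17 adjusted over the list alone; adjusted p = 0.00159, or 0.611 with an estimated correlation) and ribosomal proteins (39 fell, 1 rose, or 33 and 1 adjusted over the list alone; adjusted p = 0.00217, or 0.779 with an estimated correlation) were lower. Of the Tf2 genes 4 rose (adjusted p = 0.0398, or 0.17 with an estimated correlation). That call was lost without replicate 2 of the mutant (adjusted p = 0.0509), without WT replicate 1 (0.06) and with no filter on low counts (0.0794). Of lncRNA genes 318 rose and 138 fell (307 and 133 adjusted over the list alone; adjusted p = 0.00356, or 0.274 with an estimated correlation).

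The pfs2 alleles differed from each other in 2404 genes, of which 109 were at least 2-fold higher and 42 lower in pfs2-V180F. atd1 was higher in pfs2-V180F by 3.50 ± 0.14, str3 by 3.07 ± 0.67 and SPNCRNA.1037 by 2.85 ± 0.18. SPAC750.01 was lower by a log2 fold change of -4.05 ± 0.65. So were ftm4 (-8.22 ± 1.65) and pdc102 (-5.55 ± 0.98), each with 1 read in pfs2-V180F. ftm4 (SPAC750.05c) and SPAC750.01 have neighbouring systematic names, so these differences may not be separate. SPAC750.01 was uneven in WT as well (26.0 ± 17.5 CPM, SD, n = 3). pho1 was lower in pfs2-V180F than in pfs2-E104A by -1.17 ± 0.08 and pho84 by -1.01 ± 0.08, while tgp1 was higher by 0.45 ± 0.07. All 3 differences passed.

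In pla1-Y86L, meiotic transcripts that the RNA-binding protein Mmi1 removes in growing cells were higher. Of 11 tested, 10 rose and mcp7 fell, both over all genes and adjusted over the list alone, led by mei4 (1.51), rec8 (1.49), mug10 (1.43) and crs1 (1.34) (list adjusted p = 0.0052, or 0.212 with an estimated correlation). Of 42 snoRNA and snRNA genes, 20 rose, 19 of them at least 2-fold, and 6 fell (adjusted p = 2.1e-12, or 0.137 with an estimated correlation). snR30 rose by 2.91 ± 0.05 and snR92 by 3.01 ± 0.20. The libraries are polyA+, so such counts can also move with the polyadenylation of these RNAs. That was not separated from their level. Of lncRNA genes, 453 rose and 220 fell (445 and 211 adjusted over the list alone; adjusted p = 0.0162, or 0.346 with an estimated correlation). Among protein-coding genes with a symbol, cmt2 rose by 3.79 ± 0.13 and str1 by 3.33 ± 0.31. The amino acid permease gene nrg1 fell by 4.58 ± 0.21 and mei2, an RNA-binding protein gene that starts meiosis, by 3.95 ± 0.18. omt3, a meiosis-specific lncRNA, fell by 5.51 ± 0.33.

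Other lists also passed in pla1-Y86L. Of the iron starvation-induced genes 8 rose and 2 fell, shu1 among them (-2.32 ± 0.46), with a list adjusted p of 0.0411, or adjusted p = 0.392 with an estimated correlation. That call was lost without replicate 3 of the mutant (adjusted p = 0.0566) or WT replicate 1 (0.0678). Of genes repressed by Php4, 8 of 10 fell, led by cyc1 (-0.94) (adjusted p = 7.6e-05, or 0.17 with an estimated correlation). Ribosomal protein genes fell in 99 cases and rose in 5 (100 and 5 adjusted over the list alone; adjusted p = 8.1e-05, or 0.746 with an estimated correlation).

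In pta1-T524M heat shock chaperone genes were higher. Of 12, 11 rose and sks2 fell (-0.19), the rises led by hsp16 (1.71 ± 0.10), ssa1 (1.07), sti1 (0.99) and hsp104 (0.98), with equal counts adjusted over the list alone (list median 0.63; adjusted p = 1.9e-20, or 0.00497 with an estimated correlation). Core stress genes rose in 12 of 18 cases and none fell in the edgeR test or adjusted over the list alone, with gst2 at 3.08 ± 0.09 (adjusted p = 8.2e-10, or 0.0769 with an estimated correlation). osr1, a dehydrogenase gene, rose by 2.30 ± 0.11 and plr1 (pyridoxal reductase) by 1.88 ± 0.06. ght5 fell by 1.60 ± 0.23 and shu1 by 1.51 ± 0.40. Ribosomal protein genes fell in 78 cases and rose in 1 (94 and 1 adjusted over the list alone; adjusted p = 7.0e-10, or 0.654 with an estimated correlation). Histone genes fell in 7 of 10 cases (adjusted p = 0.00856, or 0.392 with an estimated correlation). Genes repressed by Php4 fell in 6 of 10 cases (adjusted p = 0.0182, or 0.392 with an estimated correlation), a call lost without replicate 3 of the mutant (adjusted p = 0.0552). Ribosome biogenesis factors fell in 9 of 17 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0441, or 0.714 with an estimated correlation), a call lost without replicate 2 of the mutant (adjusted p = 0.213), WT replicate 1 (0.06) or WT replicate 3 (0.169), and with the 6 libraries alone (0.0712).

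In ysh1-L74F few genes were 2-fold apart from WT. Of the genes with a symbol whose mutant libraries all lie on the same side of WT, pdc102 fell most (-2.57 ± 0.52), then pho1, and frp1 rose by 1.03 ± 0.23. In WT, pdc102 stood at only 1.13 ± 0.77 CPM (SD, n = 3). Of the iron starvation-induced genes 5 rose (adjusted p = 0.00132, or 0.234 with an estimated correlation). The calls of shu1 and fio1 were both lost without replicate 1 or 2 of the mutant or WT replicate 1 or 2, that of shu1 also without WT replicate 3, and that of php4 without replicate 1 of the mutant or WT replicate 2. Of 141 ribosomal protein genes, 93 fell and 1 rose (125 and 1 adjusted over the list alone), with a median of -0.24 (adjusted p = 6.0e-32, or 0.348 with an estimated correlation). Of 18 core stress genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0231, or 0.472 with an estimated correlation). Of 1190 lncRNA genes 139 rose and 22 fell (135 and 21 adjusted over the list alone; adjusted p = 0.00124, or 0.212 with an estimated correlation).

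In cft1-L249Q, ribosome biogenesis factors were also lower (8 of 17 fell, over all genes and adjusted over the list alone; adjusted p = 0.0441, or 0.714 with an estimated correlation). That call was lost without replicate 1 (adjusted p = 0.0976) or 2 (0.155) of the mutant, without WT replicate 1 (0.0631) or 3 (0.159), and with the 6 libraries alone (0.0693).

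**Figure D5:**
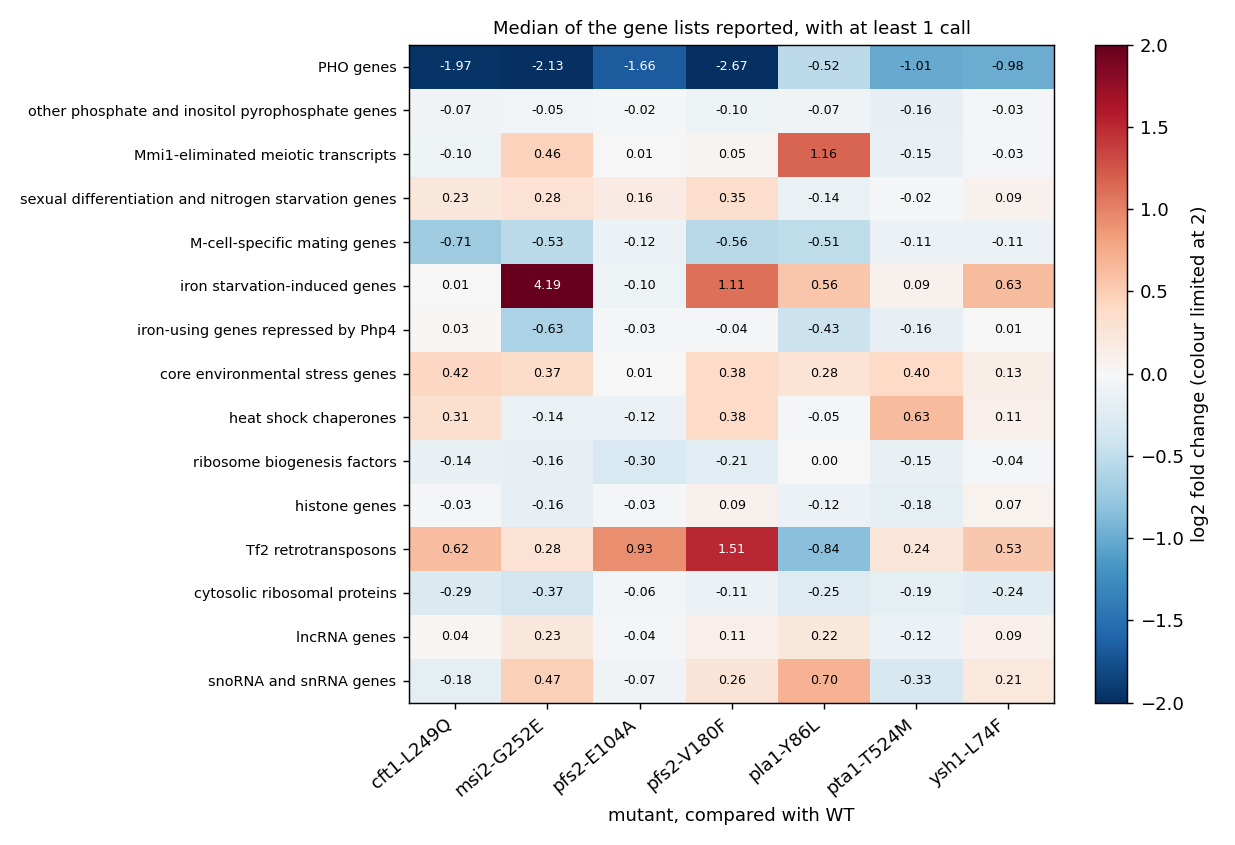
Median log2 fold change against WT of the gene lists reported here that passed in at least 1 mutant (rows), by mutant (columns), with the colour scale limited at 2. The highest median is 4.19 for iron starvation-induced genes in msi2-G252E and the lowest is -2.67 for the PHO genes in pfs2-V180F.

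In all, 50 of the 182 list tests passed, and 9 of them held with an estimated correlation: the PHO genes in 6 mutants, M-cell-specific genes in cft1-L249Q, iron starvation-induced genes in msi2-G252E and heat shock chaperones in pta1-T524M. The other calls rest on the preset correlation alone, at which lists that were not planted also passed in the simulation. The M-cell call is not separated from the h+ mating type of cft1-L249Q. The median, mean and test had the same sign in the 50 that passed, and differed in sign in 30 of the other 132. Lists that passed in no mutant, with their lowest adjusted p, were cleavage, polyadenylation and termination factors (0.281), thiamine-regulated genes (0.238), P-cell-specific genes (0.141), copper and zinc genes (0.0773), flocculin-type genes (0.435), carbon source genes (0.112), subtelomeric genes (0.0588), genes downstream of a same-strand lncRNA (0.14) or protein-coding gene (0.281), and genes with a convergent neighbour (0.384). Within the first of these, mpe1, a subunit of the same machinery, rose in 6 mutants, most in pfs2-V180F (1.16), and was at 0.07 in pta1-T524M.

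At least 2-fold in the same direction, 1 gene, SPNCRNA.1479, changed in all 7 mutants (log2 fold changes of 1.16 to 2.68). Without WT replicate 1 or 2 the count was 2. The call of SPNCRNA.1479 in pta1-T524M was lost without its replicate 1 or WT replicate 3. In at least 5 mutants 18 genes changed, 11 higher and 7 lower, and in at least 3 mutants 133. Besides SPNCRNA.1144, pho1 and pho84, they include the zinc transporter gene zrt1, which fell, and SPNCRNA.1579 and SPNCRNA.1407, which rose in 6. SPNCRNA.1479, SPNCRNA.1579 and SPNCRNA.1407 are annotated as possible alternative untranslated regions of mRNAs. Their counts were not separated from those of a neighbouring mRNA. The size of the zrt1 fall rests on WT replicate 2. Without it every zrt1 value was under 2-fold, and the calls in pfs2-V180F and pta1-T524M were lost. In ysh1-L74F, where zrt1 was at -0.88 in the main fit, its call was lost in 4 of 6 fits without 1 library. In 20 simulated datasets of unchanged mutants with the same controls, a mutant had 0.0714 calls on average, too few to test how many genes are shared. Independent lists of the observed sizes would share 1.72 higher and 0.203 lower genes in at least 3 mutants. The 7 lists are not independent, since all were set against the same 3 WT libraries. The excess over these figures is thus no measure of shared effects of the mutations. The correlation of log2 fold changes across genes, which are not independent replicates, ran over the 21 pairs of mutants from 0.02 (pfs2-E104A and pla1-Y86L) to 0.73 (cft1-L249Q and pfs2-V180F), with a median of 0.338. Unchanged simulated mutants gave, as a mean over datasets, at most 0.516 because they share the controls. The covariance was above the simulated one in 20 of the 21 pairs, the exception being pfs2-E104A and pla1-Y86L (0.00334 against 0.0109). The 3 controls cannot be split, so part of the excess may come from them.

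Genes apart both from WT and from the mean of the other 6 mutants numbered 299 in pla1-Y86L, 200 in msi2-G252E, 66 in pta1-T524M, 61 in pfs2-V180F, 37 in pfs2-E104A, 31 in cft1-L249Q and 6 in ysh1-L74F. A gene can count for more than 1 mutant, as SPNCRNA.1144, guf1 and tlh1 do, so these are not genes changed in a single mutant. Against the mean of the other mutants, shu1 was higher in msi2-G252E by 8.16 ± 0.07 and str3 by 7.76 ± 0.16. nrg1 was lower in pla1-Y86L by a log2 fold change of -5.12 ± 0.18, SPNCRNA.388 was lower in cft1-L249Q by -5.87 ± 0.33, ght5 was higher in pfs2-E104A by 3.09 ± 0.14 and SPNCRNA.1271 was higher in pta1-T524M by 3.15 ± 0.08.

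The authors' deposited tables gave 2833 genes at adjusted p under 0.05 for cft1-L249Q, 3776 for msi2-G252E, 2265 for pfs2-E104A, 3126 for pfs2-V180F, 4127 for pla1-Y86L, 2538 for pta1-T524M and 1203 for ysh1-L74F. In the authors' deposited table of msi2-G252E pho1 was at -3.24. The authors' deposited tables hold a mean above 0 for 17 genes with 0 counts in all 24 libraries, so that fit did not rest on these counts alone. No gene at least 2-fold apart in both sources had opposite directions.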

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

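The tests of the asp1 marker, of the mating type, of the cft1 mutation and of fep1 were chosen only after the results were seen.

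Genes on the fixed lists that were called in opposite directions in different mutants, with a direct contrast that also passed, drew attention as differences between groups. shu1 was 10.39 ± 0.16 (log2, SE) higher in msi2-G252E than in pla1-Y86L, ght5 3.90 ± 0.24 higher in pfs2-E104A than in pla1-Y86L, isp4 2.29 ± 0.20 higher in msi2-G252E than in pla1-Y86L, and mcp7 2.29 ± 0.09 higher in pfs2-V180F than in pla1-Y86L. tgp1 was 0.95 ± 0.07 higher in pla1-Y86L than in pta1-T524M.

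A signal also appeared in data outside the main measurement. Of 276 genes with 0 counts in every library, 17 had a mean above 0 in the authors' deposited tables, the largest being 0.136.

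SPNCRNA.1144 was higher in the 5 strains marked at asp1. Its smallest log2 fold change there exceeded the largest in the unmarked mutants by 3.84, which restates the pattern and is no test of the marker insertion, so that stays open. An effect common to the 7 mutations is argued against by the highest value in the unmarked mutants, 0.54. A constant share of asp1 reads counted for the antisense gene is argued against by the smallest excess over asp1, 3.83. A share that grew in the marked strains stays open, since the strand setting is not given and asp1 had many more reads. In WT asp1 was at 129 CPM and SPNCRNA.1144 at 0.79, and in ysh1-L74F they were at 172 and 25.9. WT lacks the marker, so differences from WT that the marked strains have in common are not separated from it. For differences that vary widely between these strains, the marker alone is argued against. The median of the iron starvation-induced genes was 4.19 in msi2-G252E, 1.11 in pfs2-V180F and 0.63 in ysh1-L74F. It was 0.09 in pta1-T524M and -0.10 in pfs2-E104A.

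mfm2 and genes beside the mating-type locus were lower in cft1-L249Q. Of 12 genes tested within 10 kb of mat1, 4 were at least 2-fold lower in cft1-L249Q, against 3 in pta1-T524M and 0 in the other 5 mutants. That goes with the h+ mating type, by a margin of 1 gene. The count hides unlike changes. SPBC23G7.10c fell by 3.54 in cft1-L249Q but rose by 2.15 in pta1-T524M. SPNCRNA.388 had at most 15 reads per library in cft1-L249Q, against at least 345 in pta1-T524M and 731 in WT. An effect of the cft1 mutation on mfm2 stays open too, since mfm2 also fell in h- mutants, the lowest at -1.96 in pla1-Y86L. Mating type and mutation coincide in this strain.

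The iron starvation-induced genes were higher in msi2-G252E, and a single library as the cause is argued against by the lowest list median without any 1 of the 6 libraries, 3.99. The lowest median with other size factors, a stricter filter or DESeq2 was 4.19 but those moved almost nothing, while a scaling error, which would move all genes of a library alike, is argued against by list members from -0.06 to 8.26 in the same libraries. A lower level of fep1 mRNA, the repressor of these genes, stays open beside an effect of the msi2 mutation. fep1 fell by 0.74 in msi2-G252E but was not called lower in 2 of the 4 mutants with the list past the threshold, pfs2-V180F (0.02) and ysh1-L74F (-0.10), whose list calls were lost with an estimated correlation (adjusted p = 0.335 and 0.234). In pla1-Y86L, also among the 4, fep1 was at -0.25, and its call was lost in 2 of 6 fits without 1 library. In pta1-T524M fep1 fell by 0.35 while the list had a median of 0.09 and did not pass (adjusted p = 0.387).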

How the results depend on the processing

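No test in this part was chosen after seeing the data except the correlation between same-numbered libraries.

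Directions and calls of pho1 and pho84 were the same under every alternative run for them, and no result reversed. With protein-coding genes alone, where fewer genes were tested, genes at least 2-fold higher and lower were 45 and 29 in cft1-L249Q, 106 and 47 in msi2-G252E, 19 and 20 in pfs2-E104A, 53 and 34 in pfs2-V180F, 100 and 67 in pla1-Y86L, 40 and 27 in pta1-T524M, and 3 higher in ysh1-L74F. With at least 50 reads in at least 3 libraries, again fewer genes, the lower counts were 24 in pfs2-E104A, 31 in pfs2-V180F and 5 in ysh1-L74F. DESeq2 gave 10 specific genes in ysh1-L74F against 6, the cause was not tested. With a 1.5-fold threshold, 6 genes were shared by all 7 mutants, 87 by at least 5 and 415 by at least 3.

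With an estimated correlation the lists past the threshold dropped to 2 in cft1-L249Q, 2 in msi2-G252E, 1 in pfs2-E104A, 1 in pfs2-V180F, 0 in pla1-Y86L, 2 in pta1-T524M and 1 in ysh1-L74F, from 8, 8, 6, 10, 6, 7 and 5 with the preset value. List calls thus depend on this choice more than gene calls do on any choice of scaling or tool.

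Without 1 of the 3 WT libraries, genes shared by all 7 mutants ranged from 1 to 2, and mutant libraries were not left out for that count. Without 1 library at a time, tgp1 ranged in pla1-Y86L from 0.14 to 0.22 and in ysh1-L74F from -0.33 to -0.23, and the ysh1-L74F gene count from 411 to 1055. Counting each named gene once per mutant and library left out, a call was lost in 415 fits and gained in 17. Counting it once per mutant, 39 calls were lost and 5 gained with 6 libraries in the fit, and 6 and 3 with DESeq2.

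The replicate number as a block moved no gene count by over 1.5 times (ysh1-L74F 995 against 906), but 2 list calls were gained, and among named genes 3 calls were lost and 2 gained. Correlations between same-numbered libraries of different groups ran from -0.19 to 0.28, so the numbers were not taken to pair the libraries. However, 15 of the 24 libraries correlated best with a library of their own number, and the mean correlation exceeded that of other pairs by 0.0455 (permutation of the numbers within groups, p = 0.0197), a hint from the data of a shared structure. Genes with few reads limit the smallest changes that can be called, and counts of list members called were not recomputed without each library.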

Other observations

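The tests of neighbouring lncRNAs were planned before their results were seen, apart from the guf1 pair, which had been noticed. The splits were also planned.

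Some protein-coding genes fell at least 2-fold where an antisense lncRNA rose at least 2-fold, these pairs being chosen after their values were seen. guf1 fell by 2.48 in cft1-L249Q, 2.85 in msi2-G252E and 2.97 in pfs2-V180F while SPNCRNA.1037, antisense to it, rose by 2.67, 3.33 and 3.52. In pla1-Y86L the arginine gene arg4 fell by 1.30 while SPNCRNA.1659 rose by 1.15. ste11, the regulator of sexual differentiation, is not among these pairs. Its mRNA fell in all 7 mutants, most in msi2-G252E (-1.62) and pla1-Y86L (-1.49). The ste11 call was lost in pfs2-E104A without its replicate 2 or 3 or WT replicate 1 or 2, and in ysh1-L74F without its replicate 1 or 2 or WT replicate 2. The counting's strand setting is not given, so antisense values carry that limit.

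The hypothesis that mRNAs fall opposite an antisense lncRNA that rose was tested over 924 genes. The mean was lower at adjusted p under 0.05 in 2 of the 7 mutants, pfs2-E104A (difference -0.14, permutation test, adjusted p = 0.0443) and pfs2-V180F (-0.10, adjusted p = 0.0443), and higher in ysh1-L74F (0.19, adjusted p = 0.0317). These means rest on 24, 76 and 9 genes with a rising antisense lncRNA, and the median of the 9 was 0.04. The asp1 locus, marked in these strains, was not left out. A fall in 2 mutants lies between the bounds set beforehand, at least 4 mutants or at most 1, and leaves the hypothesis open. For genes with an upstream same-strand lncRNA, 298 in number, the mean was lower at adjusted p under 0.05 in 0 of the 7 mutants (lowest adjusted p = 0.725). Only 3 to 46 genes per mutant lie downstream of a rising lncRNA and a missed threshold does not show that they did not fall, so the bound set beforehand was wrong and a fall there stays open.

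Other splits of the 6 libraries of each comparison were counted. With 10 splits a share under 0.05 cannot be reached. The real split was the 1 with as many genes in each comparison, with 2198 genes at adjusted p under 0.05 in cft1-L249Q, 3813 in msi2-G252E, 1779 in pfs2-E104A, 2789 in pfs2-V180F, 4026 in pla1-Y86L, 2417 in pta1-T524M, 723 in ysh1-L74F and 1948 between the pfs2 alleles, against a highest other of 0. For lists at the preset correlation, adjusted over the lists of a single comparison in a fit of its 6 libraries and so not the counts given elsewhere, the real split gave 7 in cft1-L249Q, 8 in msi2-G252E, 6 in pfs2-E104A, 10 in pfs2-V180F, 10 in pla1-Y86L, 7 in pta1-T524M and 5 in ysh1-L74F, against a highest other of 8, 8, 7, 7, 10, 11 and 7. As many lists came in 4, 3, 2, 1, 2, 3 and 4 of the 10 splits. Mixed groupings keep part of the difference between mutant and WT, so these list counts are no reference without a change.

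For each mutant against the other 6, 100 groupings of 3 libraries were compared, the real one included. As many genes at least 2-fold apart came in 1 grouping for msi2-G252E (181 genes) and for pla1-Y86L (355). They came in 2 for pta1-T524M (95) and 4 for pfs2-E104A (56). These shares are under 0.05 but were not adjusted over the mutants tested. Drawn groupings can mix libraries of different mutants, while the real one holds replicates of a single mutant. A low share thus cannot decide whether the libraries were a chance draw. For cft1-L249Q (5 groupings, 12 genes), pfs2-V180F (5, 13 genes) and ysh1-L74F (8, 1 gene) the share was not under 0.05, so chance is not excluded there either. The fit treats the other mutants as a single group, so their differences add to the spread, and its counts cannot be set beside those from the fit with a mean per mutant. The highest other grouping gave 115 genes and held 2 libraries of pla1-Y86L.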
